A study of Homo sapiens with 4 samples.

How the data were processed

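RNA was taken from 2 cultures of the BXS0116 induced pluripotent stem cell line with induced ZGLP1 and 2 with induced GFP, and total RNA libraries were made after depletion of ribosomal RNA, per the labels' protocols. Per the submitters' processing notes, CASAVA 1.4, STAR and DESeq2 were used and the genome build was hg19. The counting tool and its strand setting are not given in the sources used here. All 58721 gene identifiers equal those of GENCODE release 29, which is built on GRCh38, so the build named in the notes and the annotation disagree. Coordinates are those of GENCODE release 29 on GRCh38.

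The authors deposited a log2 fold change per gene for ZGLP1 over GFP, per the file headers. The authors deposited an unadjusted p-value per gene beside it, per the file headers. Whether the fold changes were shrunken is not stated. The direction was taken from the barcodes of both constructs, which have the signs their names require. The table has no values per library, no mean level, no standard error and no adjusted p. P-values rest on cultures that the labels call biological duplicates.

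From these values a two-sided normal statistic was computed per gene from the p-value, and the implied standard error as the fold change divided by it. The p-values were adjusted by the Benjamini-Hochberg method over the 32145 genes with a p, leaving out both barcodes, and 0.05 was the threshold. Intervals are at 95%. On simulated statistics with the real implied standard errors over 32145 genes, 23 of 100 genes changed by 1 on the log2 scale were recovered. Of those changed by 2, 81 of 100 were recovered, and 2 unchanged genes were called. All changed genes were drawn from the 15177 genes with an implied standard error under 1. Recovery among less precise genes was not simulated.

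Groups, tests, alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. Named genes are ZGLP1, the 12 largest increases and the 12 largest decreases past the threshold, up to 4 members of each list with the smallest adjusted p under 0.05, and 16 fixed genes whatever their p. The planned rule asked the largest changes for a mean of at least 50. As no mean is given, an implied standard error under 1 took its place. Transcripts that the rules on human samples hold back were left out. Any gene outside the rule was chosen after its values were seen.

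Each list was tested against all other genes with cameraPR (limma 3.58.1 in R 4.3.3) on the statistic, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over 28 lists. A correlation cannot be estimated without values per library, so 0.05 and 0.1 were tried instead. Genes are not replicates, and this test describes a list against other genes in these libraries. Calls were compared with those of other genes by a two-sided Fisher's exact test and with 10000 random lists matched on implied standard error. On simulated statistics over 32145 genes the 1 shifted list of 28 was the 1 that passed. These statistics were independent between genes, so this does not show how often a list of correlated genes would pass.

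Relative size factors were fitted to the 8 values of genes with 1 read in 1 library. The fit assumed a negative binomial model with the largest dispersion at 10 and the smallest fitted mean at 0.5, as default settings of the submitters' tool, with 3 free factors, and its largest residual was 8.08e-05 on the log2 scale. Genes with 2 reads in 1 library were then looked for at the predicted fold change. A first match, within 0.001 in fold change and 0.01 in implied standard error, found 426 genes for 1 library and 0 for the other 3. A tolerance of 0.002 in fold change alone, set after that, found 125, 116, 426 and 124 genes. The predicted standard error was met in 1 library only, so the assumed dispersion does not hold for the 2-read genes of the others and the size factors rest on the single-read genes.

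Planned filters on a mean of 10 and 50 could not be run and were replaced by limits on the implied standard error. Alternatives chosen after seeing the data are those limits, a trend over transcript length and GC share in 20 bins, centring on precisely measured genes, matching of random lists on implied standard error and a rescaled statistic within precise genes. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.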

Results

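Gene expression was measured by RNA sequencing in BXS0116, an established human induced pluripotent stem cell line kept in feeder-free culture. Doxycycline at 1 µg per ml switched on either ZGLP1, a zinc finger protein of the GATA-like family with a known part in the oogenic fate of mouse germ cells, or a green fluorescent protein (GFP) that served as control. There were 2 libraries with ZGLP1 and 2 with GFP, described in the labels as biological duplicates. The labels give the induction time as 48 hours in one field and 3 days in another. The data held are the authors' own comparison, with a log2 fold change and a p-value per gene. Values per library were not analysed here, so no total count per library can be given. Of 58721 genes in the authors' deposited table, 32145 (54.74%) have both values and 26576 have neither.

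Relative depth could be read from genes whose fold change and p repeat exactly across the table, as genes with 1 read in 1 library do. The size factors recovered this way, with a geometric mean of 1, were 0.981 and 0.973 for the GFP libraries and 1.15 and 0.911 for the ZGLP1 libraries. Which replicate is which cannot be read from the table. The standard error implied by each fold change and its p ranged from 0.209 to 5 on the log2 scale, with a median of 1.16. It lay under 0.5 for 11609 genes and at 2 or more for 12357 genes.

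**Figure D1:**
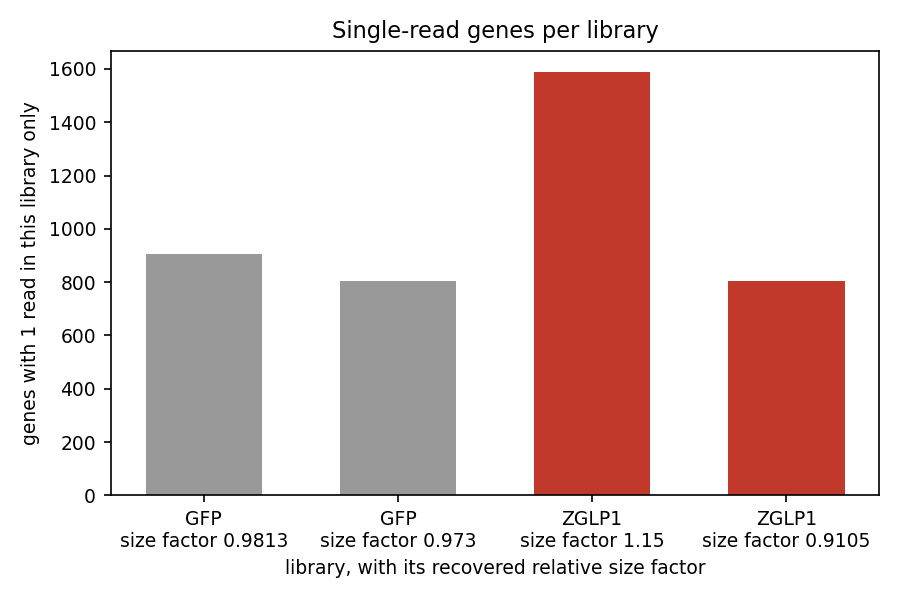
Number of genes with 1 read in the library shown and none in the other 3, for the GFP libraries (grey) and the ZGLP1 libraries (red), with the relative size factor of each library. The bars stand at 904 and 803 for GFP and at 1589 and 804 for ZGLP1.

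The comparison of ZGLP1 with GFP asks which transcripts differ between pluripotent stem cells with induced ZGLP1 and those with induced GFP. No uninduced culture is among these samples. Any other difference between the ZGLP1 and GFP cultures therefore cannot be told apart from an effect of ZGLP1. The induced gene itself was higher: in the authors' deposited table ZGLP1 (ENSG00000220201.7, chromosome 19, 10304803 to 10309880, minus strand) has a log2 fold change of 3.20, with an implied standard error of 0.82 and a 95% interval of 1.60 to 4.81. Its p of 8.93e-05 in the authors' DESeq2 comparison became 0.0105 after Benjamini-Hochberg adjustment and 1 after Holm adjustment, so its call holds under the first only. The barcode carried by each construct moved with its label, at 10.35 for the ZGLP1 barcode and -10.34 for the GFP barcode in the authors' deposited table. These last values may stand against a group with no reads and set no bound. Reads of the construct and of the endogenous ZGLP1 gene cannot be separated in the gene's value.

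Among the largest increases were COL2A1 (4.40 ± 0.80) and ACAN (4.24 ± 0.66), which encode the main collagen and proteoglycan of cartilage, in the authors' deposited table, where ± gives the implied standard error on the log2 scale. The endothelin receptor gene EDNRB (chromosome 13, 77895481 to 77975529) fell by 3.23 ± 0.32 and DDIT4, an inhibitor of mTORC1 signalling induced by stress, fell by 2.61 ± 0.28 in the authors' deposited table. LINC00458, a long non-coding RNA found in pluripotent cells, fell by 2.36 ± 0.27 in the authors' deposited table. After Benjamini-Hochberg adjustment of the authors' DESeq2 p-values, 509 genes passed 0.05, of which 350 were higher and 159 lower with ZGLP1.

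Among the 12 genes with the largest increases and an implied standard error under 1 in the authors' deposited table were PLCE1 (5.17), a phospholipase C, SYNE3 (4.95), a nuclear envelope protein, and LYST (4.85), a regulator of lysosomal trafficking. The folate receptor FOLR1 (3.87), the signalling adaptor PAG1 (3.76) and the guanosine monophosphate reductase GMPR (3.76) followed in the authors' deposited table. CCDC92 (3.84) and DNAH10OS (4.27) overlap on the same strand, so their reads may be shared and both values in the authors' deposited table are uncertain. TPTEP1 (4.57) and GRAP (3.99) have near-identical copies and their values in the authors' deposited table are uncertain for that reason. Among the 12 largest decreases in the authors' deposited table were LINC00836 (-2.74), AP000688.2 (-2.49), the bombesin receptor GRPR (-2.47), the GABA receptor subunit GABRP (-2.47) and AC003975.1 (-2.26). PTPRB (-2.14), DHRS2 (-2.13), CLDN11 (-2.13) and PCDH10 (-2.11) completed these decreases in the authors' deposited table. The median change was 1.74 among higher and -1.25 among lower calls on the log2 scale. Of the called genes, 329 higher and 125 lower ones changed by at least 1 on that scale.

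**Figure D2:**
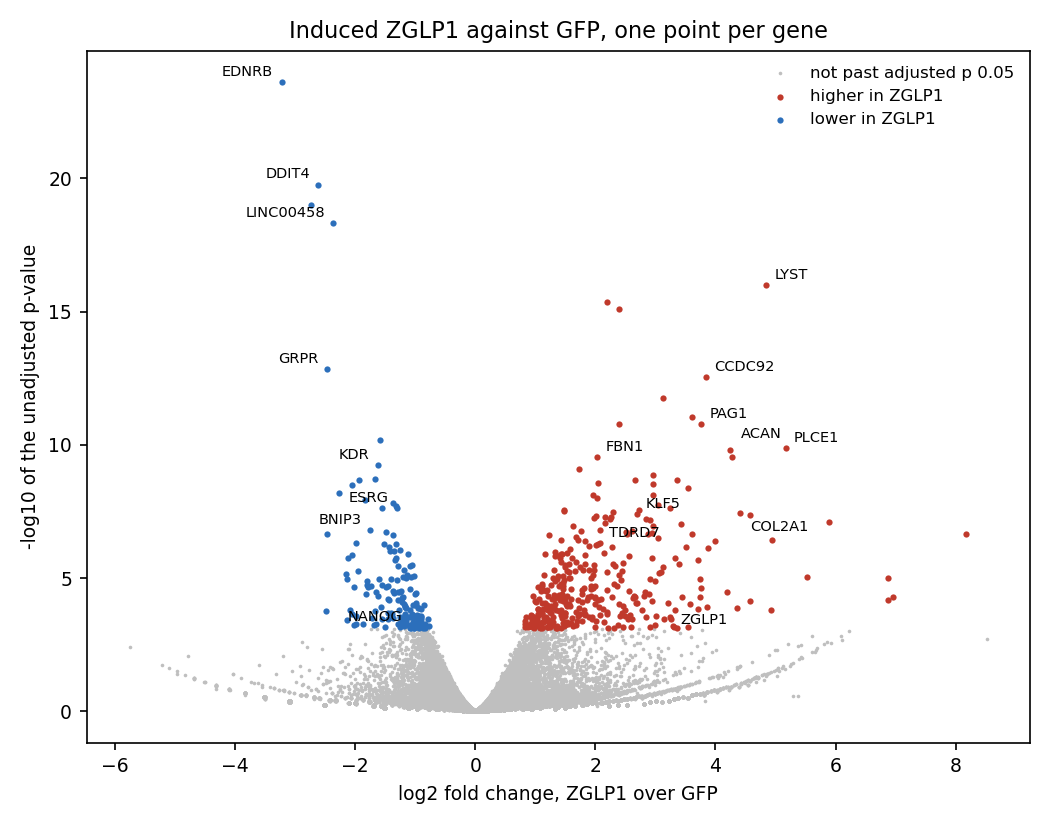
Log2 fold change of ZGLP1 over GFP against -log10 of the unadjusted p-value in the authors' deposited table, 1 point per gene, with the 350 higher genes in red, the 159 lower genes in blue and all others in grey. EDNRB lies at -3.23 and LYST at 4.85 on the horizontal axis, and ZGLP1 itself at 3.20.

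With the statistic rescaled by its central spread over all genes, 1033 genes were higher and 971 lower, a higher share of 51.55% against 68.76%. That spread takes in 12357 genes with an implied standard error of 2 or more, 4100 of them single-read genes. The statistic of a single-read gene is small whatever its true change, so this scaling may be too narrow for the other genes. The same rescaling within genes of an implied standard error under 0.5 gave a higher share of 68.57% among 35 calls, and centring on precisely measured genes (implied standard error under 0.5) gave 77.43%. Without rescaling, genes with an implied standard error under 1 gave 479 higher and 270 lower calls (63.95% higher) and those under 0.5 gave 342 and 266 (56.25%), each with fewer genes tested. Lower calls rose from 159 in both, while higher calls went from 350 to 479 and 342. Of the 509 calls, those above an implied standard error of 0.6 were 77 higher and 1 lower.

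Genes of the pluripotent state fell as a group. Of 32 measured members of the core and primed pluripotency list, 6 fell, 1 rose and 25 did not pass. NANOG, a core factor of the pluripotency network, stood at -1.07 ± 0.32 in the authors' deposited table, with ESRG (-1.30 ± 0.23), an RNA from an endogenous retrovirus, DPPA2 (-2.05 ± 0.56) and the chromatin factor UTF1 (-2.01 ± 0.58). PODXL (-0.90) and the de novo methyltransferase DNMT3B (-0.87) were the other members that fell in the authors' deposited table. NODAL, a TGF-beta family ligand, rose by 1.05 ± 0.30 in the authors' deposited table. POU5F1 (-0.70 ± 0.27) and SOX2 (-0.40 ± 0.29) have adjusted p of 0.246 and 0.962 by Benjamini-Hochberg adjustment of the authors' DESeq2 p-values. With the p adjusted over the list alone, 18 members were lower and 1 was higher. The list lay below other genes in the set test (limma cameraPR, median -0.78 on the log2 scale, adjusted p = 4.48e-20). Adjusted p = 1.11e-06 with a preset correlation of 0.1. NANOG lost its call when the fold changes were centred on precisely measured genes (adjusted p = 0.0714). ESRG overlaps CACNA2D3 on the opposite strand, and the strand setting is not given in the sources used here.

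Glycolytic and hypoxia-induced genes fell as well: of 30 measured members, 6 fell, none rose and 24 did not pass. BNIP3, a mitophagy receptor, fell by 1.75 ± 0.33 and lactate dehydrogenase LDHA by 1.15 ± 0.26 in the authors' deposited table. SLC2A3, a glucose transporter, fell by 0.85 ± 0.22 in the authors' deposited table, where DDIT4 belongs to this list too. Adjusted over the list alone, 14 members were lower and 2 higher. The list median was -0.54 on the log2 scale and the set test gave an adjusted p of 4.48e-20 (limma cameraPR), with adjusted p = 1.11e-06 at a preset correlation of 0.1. Both lists also held more lower calls than other genes by Fisher's exact test (adjusted p = 3.04e-07 for each).

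Chaperones of the heat shock list lay lower as a group without a single call. Of 20 members none passed, while 11 were lower and 1 higher at an unadjusted p under 0.05, and adjusted over the list alone 10 were lower and 1 higher. The median was -0.54 on the log2 scale (limma cameraPR, adjusted p = 2.37e-08; adjusted p = 0.00142 with a preset correlation of 0.1), but with the fold change in place of the statistic the list did not pass (adjusted p = 0.291). Of 47 measured replication-dependent histone genes, 2 fell: HIST1H1D by 1.05 ± 0.22 and HIST1H3A by 0.83 ± 0.25 in the authors' deposited table. When adjusted over the list alone, 3 were lower and none higher. HIST1H4J (-1.35 ± 0.33) and HIST1H4K (-1.17 ± 0.32), histone genes outside the list that were picked after their values were seen, fell too in the authors' deposited table. Histone genes share near-identical sequence, so single members are uncertain. The list lay lower (median -0.32, limma cameraPR, adjusted p = 9.93e-11; adjusted p = 0.0036 with a preset correlation of 0.1), but with the trend over transcript length and GC share removed its median was -0.03 and its adjusted p 0.0552. The 13 mitochondrially encoded mRNAs lay higher (median 0.36, limma cameraPR, adjusted p = 3.09e-04; adjusted p = 0.0247 with a preset correlation of 0.1), but did not pass with the fold change in place of the statistic (adjusted p = 0.879). Their median was 0.66 with the trend over transcript length and GC share removed. None of them passed on its own, 5 were higher and 0 lower at an unadjusted p under 0.05, and adjusted over the list alone 2 were higher.

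**Figure D3:**
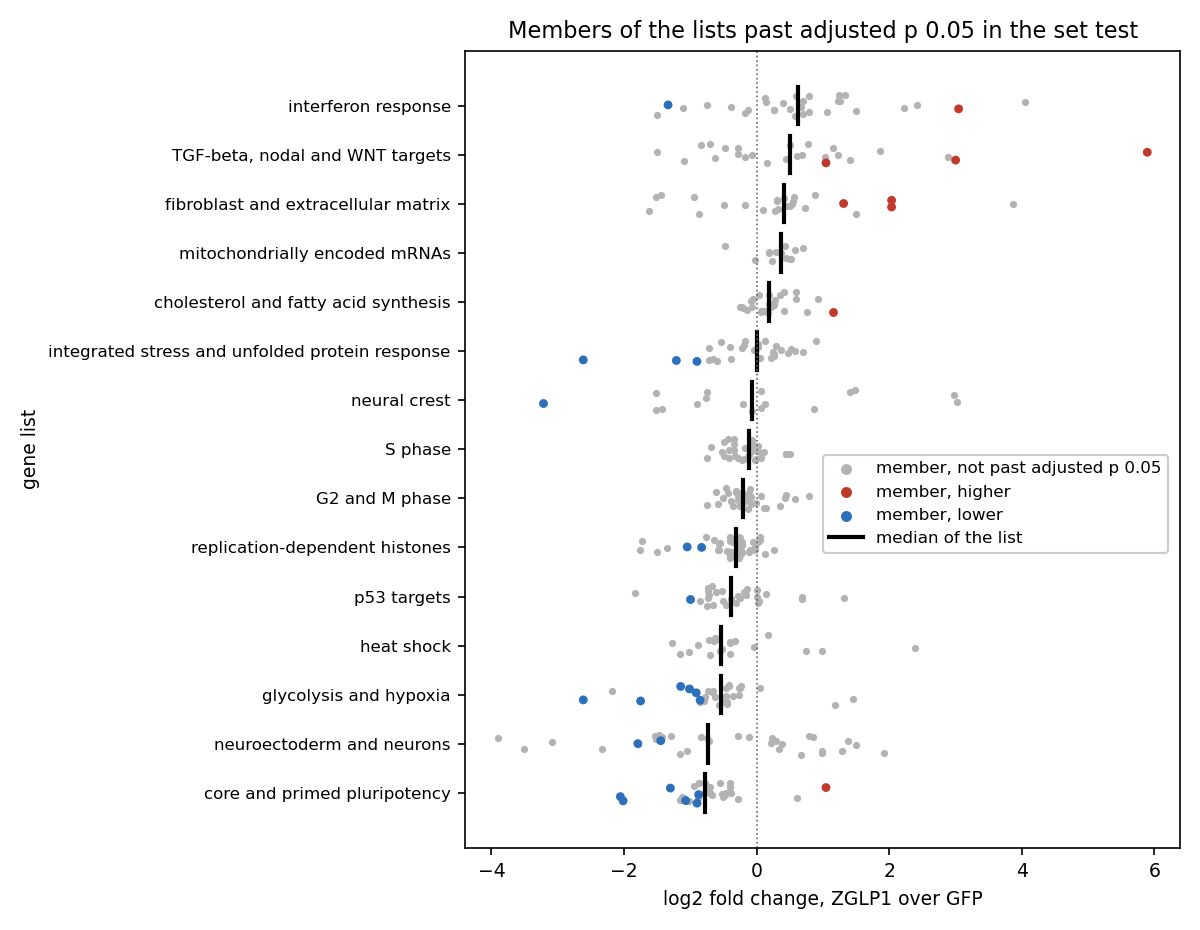
Log2 fold change of ZGLP1 over GFP for the members of the 15 gene lists past adjusted p 0.05 in the set test, with members past adjusted p 0.05 in red (higher) or blue (lower), other members in grey and the list median as a black bar. The median lies at -0.78 for core and primed pluripotency and at 0.63 for interferon response.

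Another 10 lists passed the set test at the preset correlation of 0.01 but not at 0.1. Matrix genes of the fibroblast list included 3 that rose and none that fell among 25: fibrillin FBN1 (2.04 ± 0.32), the metalloproteinase inhibitor TIMP3 (2.04 ± 0.36) and COL5A1 (1.31 ± 0.34) in the authors' deposited table. TIMP3 overlaps SYN3 on the opposite strand. Taken by itself (adjusted over the list alone), 4 were higher and 2 lower (limma cameraPR, adjusted p = 0.0031, and adjusted p = 0.169 with a preset correlation of 0.1). The list of TGF-beta, nodal and WNT targets held 3 higher genes and none lower among 25: SP5 (5.89 ± 1.10) and NKD1 (3.00 ± 0.87), both targets of WNT signalling, and NODAL, from the authors' deposited table. Adjusted over the list alone 6 were higher and 1 lower (limma cameraPR, adjusted p = 0.010, and adjusted p = 0.204 with a preset correlation of 0.1). Both lists held more higher calls than other genes by Fisher's exact test (adjusted p = 0.0276 for each), but not against random lists matched on implied standard error (adjusted p = 0.178 for each).

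Of 34 neuroectoderm and neuronal genes 2 fell, the transcription factors POU3F1 (-1.79 ± 0.42) and GBX2 (-1.45 ± 0.40) in the authors' deposited table, and none rose. When adjusted over the list alone, 6 were lower and 1 higher (limma cameraPR, adjusted p = 0.00518, and adjusted p = 0.204 with a preset correlation of 0.1). Of 17 neural crest genes EDNRB alone fell and none rose, with 3 lower adjusted over the list alone (limma cameraPR, adjusted p = 0.00976, and adjusted p = 0.195 with a preset correlation of 0.1). Of 29 p53 targets the pro-apoptotic BAX fell by 1.01 ± 0.28 in the authors' deposited table and none rose. Taken by itself (adjusted over the list alone), 5 were lower and 1 higher (limma cameraPR, adjusted p = 1.14e-04, and adjusted p = 0.0624 with a preset correlation of 0.1). In the list of the integrated stress and unfolded protein responses, DDIT4, the glycoprotein hormone STC2 (-1.21 ± 0.35) and the lipoprotein receptor VLDLR (-0.90 ± 0.25) fell among 30 in the authors' deposited table, and none rose. VLDLR overlaps an antisense gene. Adjusted over the list alone 3 were lower (limma cameraPR, adjusted p = 0.0112, and adjusted p = 0.222 with a preset correlation of 0.1). This list held more lower calls than other genes by Fisher's exact test (adjusted p = 0.00816), but not against random lists matched on implied standard error (adjusted p = 0.0635).

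The S phase list and the G2 and M phase list held no single call. Among 34 S phase genes 0 passed and 3 were lower at an unadjusted p under 0.05 (median -0.12, limma cameraPR, adjusted p = 0.00494, and adjusted p = 0.204 with a preset correlation of 0.1). Among 35 G2 and M phase genes 0 passed, with 4 lower and 1 higher at an unadjusted p under 0.05 (median -0.20, limma cameraPR, adjusted p = 0.00904, and adjusted p = 0.222 with a preset correlation of 0.1). With the trend over transcript length and GC share removed, the median of the latter was -0.11 and its adjusted p 0.210 (limma cameraPR). In both lists 0 passed when adjusted over the list alone. Of 28 genes of cholesterol and fatty acid synthesis the sterol reductase TM7SF2 rose by 1.15 ± 0.26 in the authors' deposited table, and adjusted over the list alone 2 were higher (limma cameraPR, adjusted p = 0.00533, and adjusted p = 0.204 with a preset correlation of 0.1). Of 30 interferon response genes OAS3, an antiviral oligoadenylate synthetase, rose by 3.05 ± 0.54 and IFITM1, which overlaps IFITM2 on the same strand, fell by 1.33 ± 0.28 in the authors' deposited table. When adjusted over the list alone, 1 was higher and 1 lower (limma cameraPR, adjusted p = 0.0460, and adjusted p = 0.366 with a preset correlation of 0.1).

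Germ line lists did not pass the set test. An implied standard error under 0.5 was met by 4 of 32 late germ cell, 14 of 48 meiosis and 6 of 30 oocyte genes. It was met by 10 of 25 primordial germ cell and 3 of 23 gonadal somatic genes, so changes in other members could go undetected. Of 32 measured genes of late germ cells and the piRNA pathway 1 rose, the tudor protein TDRD7 (2.09 ± 0.41 in the authors' deposited table), and none fell. Taken by itself (adjusted over the list alone), 1 was higher and 1 lower (limma cameraPR, adjusted p = 0.230). At an unadjusted p under 0.05, 4 of its members were higher and 1 lower, and the list median was 0.40 on the log2 scale. Of 48 measured meiosis genes 1 rose, the synaptonemal complex gene SYCP2 (3.01 ± 0.82 in the authors' deposited table), and none fell, also when adjusted over the list alone (limma cameraPR, adjusted p = 0.707). Of 30 oocyte and folliculogenesis genes 0 passed, also when adjusted over the list alone, and 1 was lower at an unadjusted p under 0.05 (limma cameraPR, adjusted p = 0.101). With the trend over transcript length and GC share removed this list passed as lower (adjusted p = 0.0385). Of 25 primordial germ cell genes the transcription factor TFCP2L1 rose by 1.90 ± 0.38 and UTF1 fell in the authors' deposited table, with the same counts adjusted over the list alone (limma cameraPR, adjusted p = 0.541). Of 23 gonadal somatic genes 0 passed, also when adjusted over the list alone, and 1 was higher at an unadjusted p under 0.05 (limma cameraPR, adjusted p = 0.491).

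Single germ line genes varied in precision. PRDM1 (0.86 ± 0.99), TFAP2C (-0.39 ± 0.36), DAZL (-1.48 ± 0.92) and the meiotic cohesin REC8 (0.03 ± 0.32) did not pass in the authors' deposited table. NANOS3 (-2.50 ± 4.77) has the value of a gene with 2 reads in 1 GFP library and SYCP3 (2.22 ± 4.91) that of a gene with 2 reads in 1 ZGLP1 library in the authors' deposited table, so no change was detectable at this depth. For SOX17, DDX4, STRA8 and FIGLA the authors' deposited table lists neither value.

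Lists of other lineages gave few calls. Among 15 naive pluripotency genes KLF5 (2.70 ± 0.49) and TFCP2L1 rose and DPPA2 fell in the authors' deposited table, with the same counts adjusted over the list alone (limma cameraPR, adjusted p = 0.384; as higher, adjusted p = 0.00111 on its 3 members with an implied standard error under 0.5). Those 3 are KLF5, TFCP2L1 and TFAP2C (-0.39), with DPPA2 outside the limit, so this value restates the 2 higher calls. Among 30 amnion and trophoblast genes the hypoxia-inducible factor EPAS1 (1.95 ± 0.44) and the aminopeptidase ENPEP (2.70 ± 0.69) rose and GABRP fell in the authors' deposited table (limma cameraPR, adjusted p = 0.230). Adjusted over the list alone 2 were higher and 2 lower. Among 25 primitive streak and mesoderm genes SP5 rose and the VEGF receptor KDR (-1.62 ± 0.26) fell in the authors' deposited table, with the same counts adjusted over the list alone (limma cameraPR, adjusted p = 0.442). KDR was also the only call among 33 blood and endothelium genes, where 1 was higher and 1 lower adjusted over the list alone (limma cameraPR, adjusted p = 0.230). Among 23 definitive endoderm genes ONECUT1 (-1.99 ± 0.55 in the authors' deposited table) fell and none rose, with 1 higher and 1 lower adjusted over the list alone (limma cameraPR, adjusted p = 0.384). Among 26 BMP signalling targets 0 passed, also when adjusted over the list alone, with 3 higher and 4 lower at an unadjusted p under 0.05 (limma cameraPR, adjusted p = 0.541). Of its 8 members with an implied standard error under 0.5, 7 had a negative fold change, and on these the list passed as lower (limma cameraPR, adjusted p = 0.0136). That limit, chosen after the data were seen, left out the 3 members that were higher at an unadjusted p under 0.05. They were BMP4 (1.42), SMAD9 (1.33) and DLX3 (2.97) in the authors' deposited table, so the lower result depends on the limit. ID1, a BMP target, stood at -0.45 ± 0.29 in the authors' deposited table.

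Of 26 genes of DNA methylation and germ line silencing the dioxygenase TET2 (1.49 ± 0.37) rose, and TET1 (-0.79 ± 0.22) and DNMT3B fell in the authors' deposited table, with the same counts adjusted over the list alone (limma cameraPR, adjusted p = 0.256). Of 15 genes of the GATA and GATA-like family only ZGLP1 passed, also when adjusted over the list alone (limma cameraPR, adjusted p = 0.386). GATA4 (0.47 ± 2.82) and GATA6 (-1.70 ± 3.41) were too imprecise in the authors' deposited table for a change to be detectable. In 6 lists the median, the mean and the set test differed in sign: naive pluripotency, oocyte, BMP, definitive endoderm, blood and endothelium, and the stress response list.

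Which lists passed the set test depended on the setting. With the fold change in place of the statistic 4 of the 15 stayed: core and primed pluripotency (limma cameraPR, adjusted p = 0.00412), glycolysis and hypoxia (0.0143), histones (0.0283) and neuroectoderm (0.0143). Among genes with an implied standard error under 0.5, 8 of the 15 stayed. Those that did not were p53 targets (limma cameraPR, adjusted p = 0.0505), neuroectoderm (0.0763), the stress response list (0.156), S phase (0.160), G2 and M phase (0.203), TGF-beta, nodal and WNT targets (0.650) and interferon response (0.882). With ranks in place of the statistic 11 stayed, without neuroectoderm (limma cameraPR, adjusted p = 0.0728), TGF-beta, nodal and WNT targets (0.216), the stress response list (0.423) and neural crest (0.605).

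Holm adjustment ended the calls of 32 named genes, ZGLP1 and NANOG among them. Several calls near the threshold ended under other scalings of the authors' values. With centring on precisely measured genes the Benjamini-Hochberg adjusted p was 0.0575 for PODXL, 0.0521 for VLDLR, 0.0552 for STC2, 0.0851 for HIST1H3A, 0.0548 for TET1 and 0.0807 for DNMT3B. With the trend over transcript length and GC share removed it was 0.0504 for NANOG, 0.0526 for DPPA2, 0.0779 for UTF1, 0.0792 for BAX, 0.0582 for HIST1H1D, 0.457 for HIST1H3A, 0.0511 for TET1 and 0.0519 for NKD1.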

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

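Tests with limits on the implied standard error, the length and GC trend, centring, matched random lists and the rescaling within precise genes were chosen after the data were seen. No paired analysis was possible because the table has no values per library, and for that reason leaving out a replicate, a replicate block, another tool and other pseudocounts were not run. Filters on a mean were not run because no mean is given. Against 509 called genes, 350 higher and 159 lower, an adjusted p under 0.01 gave 269 (196 and 73), Holm adjustment 107 (78 and 29) and the test of a change beyond 1 on the log2 scale 23 (18 and 5), each a stricter criterion by construction. An adjusted p under 0.1 gave 260 lower genes. Rescaling the statistic by its central spread gave 2004 (1033 and 971) over all genes and 35 (24 and 11) within an implied standard error under 0.5, so the count depends on the assumed null. Without rescaling, genes with an implied standard error under 0.5 gave 608 calls, so rescaling lowered the count there and raised it over all genes. Leaving out the imprecise genes thus reversed the effect of rescaling on the count. How far the single-read genes alone account for this was not tested. Limits on the implied standard error of 1 and 0.5 gave 749 (479 and 270) and 608 (342 and 266), with fewer genes tested. Direction could turn only under centring, the trend correction and the rescaled statistics, since the other settings keep the sign of the fold change. No call turned under those. Centring kept 473 of the 509 calls and the trend correction 441. ZGLP1 stayed between 2.32 and 3.27 on the log2 scale, but its Holm adjusted p was 1, and Holm adjustment ended the calls of 32 named genes in all. Of the 28 lists 15 passed, against 7 and 5 with a preset correlation of 0.05 and 0.1 and 4 with the fold change in place of the statistic, and the cause was not tested for the last. Ranks kept 11. Genes with an implied standard error under 0.5 gave 10 of 27 lists, 8 of them among the 15, and the trend correction 14, 13 of them among the 15. Fisher's exact test passed 5 list and direction pairs, against 2 with matched random lists. No list or named gene reversed past its threshold. Precision limits many genes: 12357 of 32145 have an implied standard error of 2 or more.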

Other observations

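The tests of size factor, of dilution, of the length and GC trend, of shared reads and of copy number were chosen only after the results or the data were seen, as were the gene groups and classes named here. The rules for coding share and for the length and GC trend were set before the results they judge.

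Of 44 collagen genes 5 rose, 0 fell and 39 did not pass. Those that rose were COL2A1, COL22A1 (2.85), COL11A2 (2.19), COL4A5 (0.93) and COL5A1, the last also a member of a fixed list, in the authors' deposited table. The group lay above other genes (median 0.58 on the log2 scale, limma cameraPR, p = 1.32e-08; p = 0.00314 with a preset correlation of 0.1). Of 83 ribosomal protein genes 0 passed, while 42 were lower and 0 higher at an unadjusted p under 0.05, and 82 of the 83 had a negative fold change (limma cameraPR, p = 5.23e-31; p = 2.50e-07 with a preset correlation of 0.1). Their median was -0.45 on the log2 scale, and -0.27 with the length and GC trend removed. The mitochondrial ribosomal RNAs MT-RNR1 (1.33 ± 0.34) and MT-RNR2 (1.07 ± 0.31) were higher in the authors' deposited table. Ribosomal RNA was depleted from these libraries, so both values may depend on the depletion and need not stand for transcript level. Of 222 ZNF-symbol genes on chromosome 19, 0 passed, with 17 lower and 5 higher at an unadjusted p under 0.05 (median -0.18, limma cameraPR, p = 1.37e-04; p = 0.155 with a preset correlation of 0.1).

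Among genes with an implied standard error under 0.5, 22 of 123 lincRNAs (17.9%) were called lower against 129 of 11486 other genes (1.12%, Fisher's exact p = 2.57e-19), and 0 lincRNAs were called higher against 234 other genes (Fisher's exact p = 0.184). Without that limit, 23 of 3057 lincRNAs were lower (0.752%, against 0.468% of other genes, Fisher's exact p = 0.0409) and 3 were higher (0.0981%, against 1.19%, Fisher's exact p = 1.06e-11). Only 123 of the 3057 lincRNAs met the limit, against 11486 of 29088 other genes, so the classes differ in how many genes could be called. They were not matched on implied standard error, and these tests do not separate class from precision. The 3 higher lincRNAs were MIR29B2CHG (2.68 ± 0.69), MIR22HG (2.65 ± 0.65) and LINC01806 (2.10 ± 0.52) in the authors' deposited table. On chromosome 15 SNHG14 (-0.90 ± 0.25), AC124312.4 (-1.26 ± 0.36), PWAR5 (-1.32 ± 0.28), AC124312.5 (-1.43 ± 0.36), PWAR6 (-1.37 ± 0.24) and SNORD116-13 (-1.26 ± 0.37) were lower in the authors' deposited table. SNRPN had a fold close to that of SNHG14 (-0.88 ± 0.29) without passing, and UBE3A (-0.05 ± 0.24) and NDN (0.21 ± 0.28) did not pass in the authors' deposited table. The other 5 called genes lie within SNHG14 on the same strand, so reads counted for one can belong to another. Called genes with an implied standard error of 1 or more included GALNT5 (8.18 ± 1.58), SLC40A1 (6.95 ± 1.72) and PPARG (5.52 ± 1.24) in the authors' deposited table.

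Core pluripotency and glycolysis genes were lower together. A trend with transcript length and GC share may lower short transcripts. The shift of the histone list was largely lost with this trend removed, but histone genes were among the precise genes that set the trend. That loss therefore does not show the trend acting on them. With that trend subtracted the medians of these lists stayed at -0.62 and -0.48 on the log2 scale and both passed the set test, which argues against the trend as the whole cause. Dilution by cells that lack these transcripts would lower all members by a common factor. The 27 precise members of the pluripotency list differed beyond their errors (heterogeneity statistic of 69.5 against a critical value of 38.9, and more so in the glycolysis list). Of these 27, however, 25 were negative and 2 positive, NODAL (1.05) and LEFTY2 (0.61), in the authors' deposited table. The test was not run on the falling members alone. It therefore cannot tell whether those fell by a common factor, and dilution stays open. Ribosomal protein genes were lower as well and mitochondrially encoded mRNAs higher, and 1 ZGLP1 library stood apart in its number of single-read genes. A difference in RNA composition between the libraries was not tested and stays open. A change within the cells, or other cells that express part of these lists, stays open and was not tested.

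One ZGLP1 library held 1.98 times as many single-read genes as the other (95% interval 1.82 to 2.15), and 3.44 times as many 2-read genes. The ratio of their size factors was 1.26, which lies below that interval and argues against a larger size factor as the whole cause. Background reads outside mRNA could be a source: the protein-coding share of the single-read genes was 16.4% (14.7 to 18.3) against 18.9% (16.3 to 21.8), a lower share with overlapping 95% Wilson intervals. The planned test needed intervals that do not overlap to count for background reads, and a difference smaller than their overlap to count against them. Neither was met, so this explanation stays open. No biological explanation was tested, and the intervals cover counting error only.

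Neighbouring genes were called in the same direction more often than permuted genes. Among 15152 genes with an implied standard error under 1, 19 neighbouring pairs rose together against a permuted mean of 7.57 (permutation p = 3e-04) and 15 fell together against 1.66 (permutation p = 1e-04, the smallest 10000 permutations can give). Reads shared by overlapping or adjacent genes could make such pairs, but 22 pairs lay more than 10 kb apart against an upper limit of 10 in permuted genes (95% interval). Of these, 21 had no annotated gene on their common strand that overlaps both, against the same limit of 10. A copy number change of the region would also move the other genes nearby, taken here as a median shift of at least 0.4 on the log2 scale over genes with an implied standard error under 0.5 within 1 Mb, called or not, leaving out those joined to the pair by a gene on the same strand. The 95% bootstrap interval of this shift lay below 0.4 for 7 of the 22 pairs and above it for 0. It included 0.4 for 10 pairs, and 5 had fewer than 5 such genes, among them the pair inside SNHG14. The 7 do not exceed the limit of 10 on their own, so a copy number change stays open. Regulation shared by neighbours is a candidate explanation that was not tested, found on the same data.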
